A study of Mus musculus with 8 samples.

How the data were processed

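Haematopoietic stem cells, the self-renewing cells from which blood cells arise, were sorted by flow cytometry from the bone marrow of 4 wild-type (WT) and 4 Kdm4a/b/c triple knockout (KO) mice on a C57BL6 background, 2 weeks after the knockout was induced. Each mouse gave 1 RNA-seq library. The sort markers, the way the knockout was induced and the exons deleted are not given in the sources used here. Per the labels' protocols, cDNA was made and amplified from total RNA with the Nugen Ovation system, sheared by sonication and sequenced on an Illumina NextSeq. Such amplification adds copies that carry no molecular identifier, so a count is a count of reads and not of molecules.

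The deposited values are raw counts of reads per gene symbol, 1 table per library. Per the labels' protocols, the authors mapped reads with STAR (Galaxy version 2.4.0d-2), counted them with htseq-count (Galaxy version 0.6.1galaxy1) and tested genes with DESeq2 (Galaxy version 2.1.8.3). The build named in the submitters' processing notes was mm10. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads from a gene and an overlapping antisense gene may not have been separated. Genes with near-identical copies can lose reads in such counting. All 6 globin symbols, Hba-a1, Hba-a2, Hbb-b1, Hbb-b2, Hbb-bs and Hbb-bt, were listed at 0 in every library. The tables held 24222 symbols, of which 23061 matched a gene of the GENCODE annotation of the same build by symbol, 808 matched through a synonym and 353 did not match. Coordinates are 1-based positions from that annotation.

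Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr with the group (minimum count 10, minimum total 15), which left 11498 genes. Library sizes were scaled by the trimmed mean of M-values (TMM), with factors between 0.974 and 1.03. KO was compared with WT by edgeR's quasi-likelihood test with robust dispersion, in the version that treats small counts with adjusted deviances, with genotype as the only term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Folds are from the fitted model, and the standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, counts scaled to a common TMM-adjusted library total, given as mean ± SD over 4 mice. A level of 3 counts was taken as the floor of detection in a library, which covers counting error only.

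A total of 25 gene lists were drawn up before the data were examined, covering stem cell and progenitor genes, markers of other marrow cell types, the cell cycle, p53 targets, apoptosis, ribosome biogenesis and ribosomal proteins, interferon-stimulated genes, H3K9 methylation and silencing, other histone demethylases, metabolism, stress, DNA repair, histones and imprinted genes. The 22 lists with at least 5 measured genes were compared with the other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move in a direction on balance, were alternatives. The main design, the alternatives and the rule for named genes were also fixed before the data were examined. The rule took Kdm4a, Kdm4b, Kdm4c and Kdm4d, and the study genes Taf1b and Nom1. It also took the 12 largest increases and 12 largest decreases among genes past the threshold with no overlap between WT and KO libraries and a mean of at least 5 CPM, leaving out pseudogenes and genes with a provisional symbol (Gm and a number, or ending in Rik). This left out the pseudogene C920009B18Rik and 4930515G01Rik, which rose, with log2 fold changes of 2.96 and 2.53. It also left out 2610524H06Rik, which fell, at -1.99. From each list it took up to 3 members past the threshold or, where there was none, the member with the smallest p. Some genes that the rule took are not reported here.

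The alternatives were DESeq2 size factors, library totals without TMM, no filter, a stricter filter of 5 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom with sample weights and edgeR's legacy quasi-likelihood method. Further alternatives were the replicate number as a block, offsets for gene length and GC content, counts thinned to 3594315 per library, removal of ribosomal RNA genes, and omission of each library in turn. Thresholds of adjusted p 0.1 and of log2 fold change 1 were also tried.

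The procedure was tested on simulated counts drawn from the means, library sizes and edgeR dispersions of the KO against WT comparison. A seeded set of genes was changed, and 11323 genes passed the filter. Since the spread came from edgeR's own estimates, the simulation may favour edgeR over DESeq2. At folds of 1.5, 2 and 4, edgeR recovered 19.4%, 44.8% and 90.9% of the changed genes, and 7 of its 110 calls (6.4%) were false. DESeq2 recovered 23.9%, 53.7% and 90.9%, with 27 of 139 calls (19.4%) false. Camera called the list that had been changed by 0.5 on the log2 scale and 0 of the other lists. The simulated genes were drawn independently of each other, so this does not show how camera treats lists whose genes vary together. In the real data the estimated correlation was 0.371 for the interferon list and 0.369 for the list of G2 and mitosis.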

Results

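The data were RNA-seq counts from haematopoietic stem cells of 4 WT and 4 Kdm4a/b/c triple knockout mice, taken 2 weeks after the knockout was induced. Kdm4a, Kdm4b and Kdm4c encode demethylases of methylated lysines in histone H3, among them H3K9. The comparison asks how the RNA of these cells differs after loss of the 3 enzymes. Total counts were 5902042, 3594315, 5086878 and 6044289 in WT mice 1 to 4, and 7059382, 6979889, 14872493 and 5541504 in KO mice 1 to 4. Between 13882 and 15359 genes had at least 1 count per library. Rn45s, the ribosomal RNA precursor, took 2.39% to 4.85% of WT counts and 2.37% to 3.93% of KO counts. In a principal component analysis, the first component held 20.5% of the variance. The WT libraries lay between -39.9 and -3.05 on it, and the KO libraries between 18.1 and 27.1. Within WT their order on it followed total counts, which was not so within KO. Correlations of log2 CPM were as high between groups (0.93 to 0.955) as within them (0.932 to 0.952). No pair of libraries of a group was closer than sampling noise, the smallest chi-square per degree of freedom being 10.9.

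All 3 targeted genes had lower RNA in each KO library than in any WT library. Kdm4c (chromosome 4, 74242497 to 74405860, plus strand, mm10) fell 3.27-fold, from 115 ± 22.7 to 36.0 ± 10.6 CPM (SD, n = 4), with an adjusted p of 2.05e-05 by edgeR's quasi-likelihood test. Kdm4a (chromosome 4, 118136957 to 118180043, minus strand) was at 36.3 ± 9.56 CPM in WT and 20.3 ± 3.86 CPM in KO, a log2 fold change of -0.87 (SE 0.249). Kdm4b (chromosome 17, 56326062 to 56402870, plus strand) was at 10.2 ± 2.44 and 3.73 ± 1.79 CPM, a log2 fold change of -1.40 (SE 0.416). Neither passed the threshold over all genes, with adjusted p of 0.132 for Kdm4a and 0.142 for Kdm4b by edgeR's quasi-likelihood test. The exact two-sided permutation p was 0.0286 for each of the 3 genes, the smallest that 4 against 4 libraries can give. Kdm4d, a related demethylase that was not targeted, had 0 to 9 counts per library and was not tested. The counts sum over a whole gene, so reads from exons that were not deleted are included, and Kdm4b rested on 6 to 72 counts per library.

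**Figure D1:**
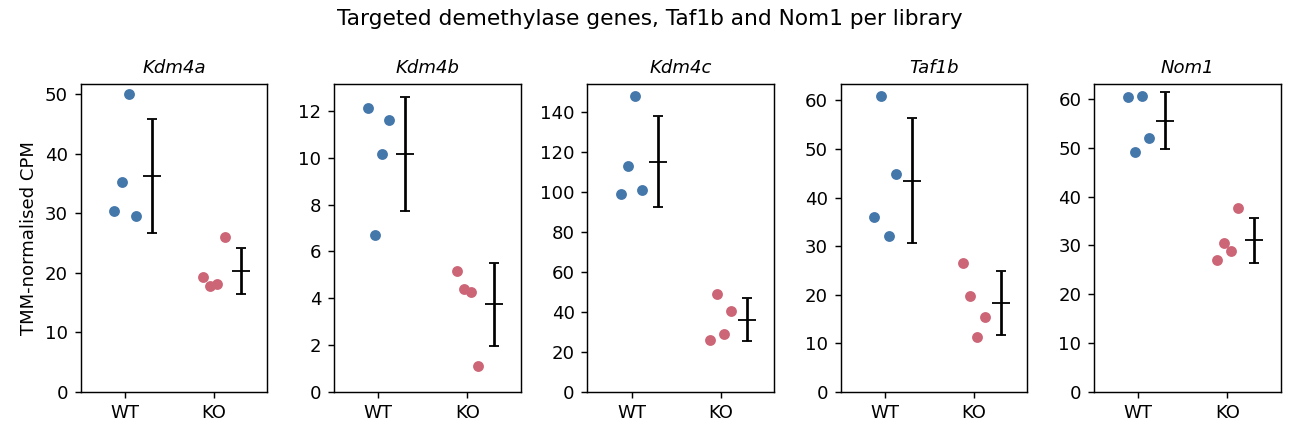
Levels of Kdm4a, Kdm4b, Kdm4c, Taf1b and Nom1 in CPM (vertical axis) in each of the 4 WT and 4 KO libraries (points), with the mean and SD of each group. For each of the 5 genes, all 4 KO libraries lie below all 4 WT libraries.

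In KO, 29 genes were higher and 38 lower than in WT among the 11498 tested. The most strongly raised included F5 and F10, which encode coagulation factors, and Cxcr2, a chemokine receptor best known from neutrophils. F5 rose 2.85-fold, from 76.2 ± 12.4 to 218 ± 14.9 CPM (SD, n = 4, adjusted p = 1.74e-06 by edgeR's quasi-likelihood test). Cxcr2 rose 4.24-fold, from 9.49 ± 3.25 to 41.3 ± 5.44 CPM, and F10 rose 5.26-fold, from 2.78 ± 1.16 to 13.4 ± 4.33 CPM. The largest fold was that of Espnl, an actin-bundling protein gene, which rose 10.1-fold but from 4 to 6 counts per WT library. Muc5b, a gel-forming mucin, rose 3.90-fold and Pcdhb16, a protocadherin, 3.57-fold. Ifi44 rose 2.29-fold, Cd180, a Toll-like receptor homologue, 2.26-fold and Slfn5, a Schlafen gene, 2.24-fold, although 8.8% of the exons of Slfn5 overlap an antisense gene. Cd68 and Cd74, known from macrophages and antigen presentation, rose 2.97-fold and 2.26-fold, and Gp1ba, a platelet receptor for von Willebrand factor, rose 2.26-fold.

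Among the genes that fell, Atf7ip and Dnah8 had the smallest p-values. Atf7ip (chromosome 6, 136506167 to 136610862), a partner of the H3K9 methyltransferase SETDB1, fell 2.38-fold, from 313 ± 42.6 to 131 ± 9.38 CPM (SD, n = 4, adjusted p = 2.56e-06 by edgeR's quasi-likelihood test). Dnah8, an axonemal dynein heavy chain, fell 3.27-fold, from 143 ± 16.5 to 42.6 ± 9.64 CPM (adjusted p = 2.39e-06 by edgeR). Thbs1, which encodes thrombospondin 1, fell 3.51-fold and Csf2ra, the alpha chain of the GM-CSF receptor, 3.44-fold. Gstm7, a glutathione transferase, fell 3.31-fold, from 15.9 ± 1.84 to 4.33 ± 2.18 CPM. The tetraspanin gene Cd63 fell 2.61-fold, Zcchc3 2.59-fold, Dpp4, a surface peptidase, 2.38-fold, the sphingosine phosphate receptor gene S1pr4 2.32-fold, and the sialyltransferase gene St6galnac3 2.20-fold.

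**Figure D2:**
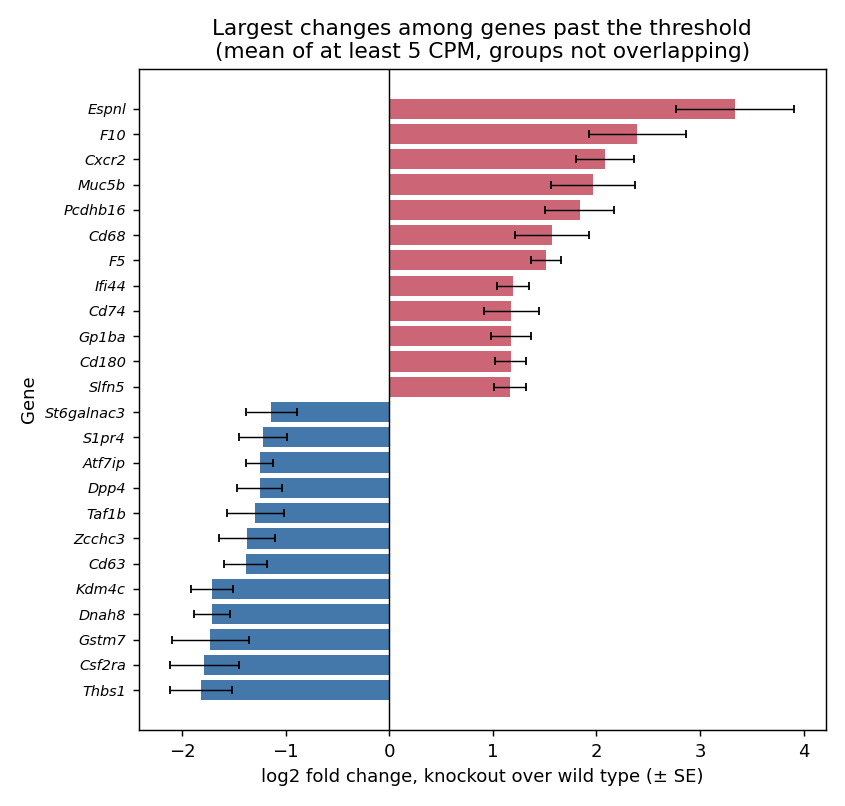
Log2 fold change of KO over WT (horizontal axis) with its SE for the 12 largest increases and 12 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between WT and KO libraries, leaving out pseudogenes and genes with a provisional symbol (Gm and a number, or ending in Rik). Within these limits the increases run from 1.16 for Slfn5 to 3.34 for Espnl, and the decreases from -1.14 for St6galnac3 to -1.81 for Thbs1.

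Of the 67 genes, 38 changed at least 2-fold, and the smallest change was 0.46 on the log2 scale. In 63 of the 67 the WT and KO libraries did not overlap. Over all genes tested, 5.8% had no overlap, against 2.86% by chance, and 11.2% had an unadjusted p under 0.05. The count of 67 fell to 35 without WT mouse 3, and to 44 without WT mouse 2 or without KO mouse 4; DESeq2 gave 154 genes. The calls of F10, Muc5b, Cd68, Cd74, Gstm7, Zcchc3, S1pr4 and St6galnac3 were each lost when at least 1 library was left out, Cd68 in 7 of the 8 cases.

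Taf1b and Nom1 fell in KO. Taf1b (chromosome 12, 24498359 to 24558539) encodes a subunit of the factor that brings RNA polymerase I to ribosomal DNA, and Nom1 (chromosome 5, 29434664 to 29457843) a nucleolar protein. Both are recalled as genes that the published study of these mice singled out, with these samples, so their direction is not independent evidence. That study was not among the sources used here, and any other evidence it gave for them is not covered. Taf1b fell 2.45-fold, from 43.5 ± 12.8 to 18.2 ± 6.53 CPM (SD, n = 4, adjusted p = 0.0226 by edgeR's quasi-likelihood test), and Nom1 1.83-fold, from 55.6 ± 5.81 to 31.0 ± 4.68 CPM (adjusted p = 0.0368 by edgeR). Both were lower adjusted over the list alone, which again is not independent evidence. The Taf1b call was lost without WT mouse 2 (adjusted p 0.119 by edgeR), WT mouse 4 (0.0651), KO mouse 3 (0.0949) or KO mouse 4 (0.0606). The Nom1 call was lost in 10 of 19 alternatives, with edgeR adjusted p up to 0.151 over them. Of 51 other genes of RNA polymerase I and ribosome biogenesis, 0 passed edgeR's test over all genes. At an unadjusted p under 0.05, 5 of them were higher and 1 lower, and DESeq2 called 3 higher and limma voom 1. Nol6, Heatr1 and Gnl3, 3 in all, were higher adjusted over the list alone. Nol6 was at 67.9 ± 17.9 CPM in WT and 107 ± 11.6 CPM in KO, and the list did not pass camera (adjusted p = 0.0728). Of 74 ribosomal protein genes 0 passed, and camera gave an adjusted p of 0.767.

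The list of interferon-stimulated genes was higher in KO by camera with the preset correlation (adjusted p = 2.32e-24), but not with an estimated one (adjusted p = 0.137 with an estimated correlation). Of 29 measured, 27 had a fold above 1 and the median log2 fold change was 0.55. Over all genes 3 rose, namely Ifi44 from 134 ± 39.9 to 314 ± 32.6 CPM, the antiviral gene Oasl2 from 301 ± 53.5 to 506 ± 43.8 CPM, and Stat2, a mediator of interferon signalling, from 60.9 ± 16.8 to 106 ± 12.9 CPM (SD, n = 4, adjusted p = 7.99e-05, 0.00178 and 0.0492 by edgeR). A total of 20 were higher and 0 lower adjusted over the list alone. At an unadjusted p under 0.05, 20 were higher and 0 lower, and DESeq2 called 10 higher and 0 lower. Fry gave the list an adjusted p of 0.0438. The mean log2 level of the list, centred per gene, was between -0.62 and 0.05 in WT and between 0.02 and 0.59 in KO, so KO mouse 3 lay below WT mouse 4. The exact permutation p of that mean was 0.0571 for n = 4 against 4. The Stat2 call was lost in 11 of 19 alternatives, with adjusted p by edgeR, DESeq2 or voom between 0.0051 and 0.178.

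The 2 cell cycle lists were higher in KO by camera with the preset correlation, with adjusted p of 4.98e-05 for S phase and 2.04e-06 for mitosis. Neither passed otherwise, with adjusted p = 0.312 and 0.317 with an estimated correlation, and 0.187 and 0.193 by fry. Of 33 genes of S phase and DNA replication, 31 had a fold above 1, with a median log2 fold change of 0.18, and of 29 genes of G2 and mitosis 25 did, with a median of 0.25. Over the alternatives these medians ran from 0.131 to 0.261 and from 0.13 to 0.324. In the mean centred log2 level of the mitotic list, KO mouse 1 was highest at 0.417. KO mouse 2 at 0.068 and KO mouse 3 at -0.066 lay below WT mouse 4 at 0.118. In the S-phase list, KO mouse 2 at -0.011 lay below WT mouse 1 at 0.089. The exact permutation p of these means was 0.0571 for S phase and 0.0857 for mitosis. Over all genes 0 of the 33 and 0 of the 29 passed edgeR's test. At an unadjusted p under 0.05, 6 and 8 were higher and 0 lower; DESeq2 called 0 and 1, and limma voom 0 and 0. No S-phase gene (0) and 2 mitotic genes were higher adjusted over the list alone. The 2 were Ckap2l, a spindle gene, at 93.6 ± 17.9 CPM in WT and 149 ± 29.7 CPM in KO, and Cenpe, a kinetochore motor. The helicase gene Mcm6 was at 474 ± 55.0 and 622 ± 94.3 CPM.

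**Figure D3:**
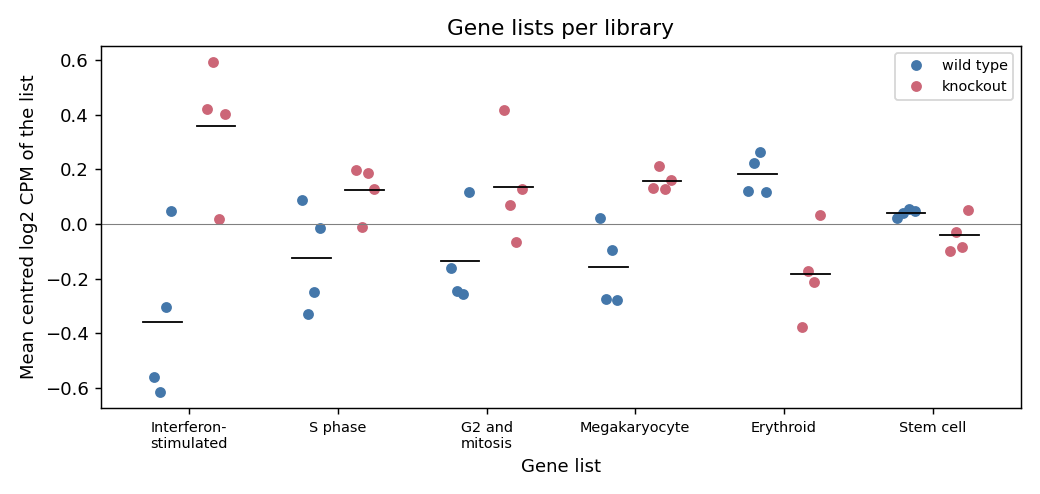
Mean log2 CPM of the genes of 6 lists, each gene centred on its mean over all libraries (vertical axis), in each of the 4 WT and 4 KO libraries (points). In the megakaryocyte list the KO libraries lie between 0.129 and 0.21 and the WT libraries between -0.28 and 0.02, while in the interferon list KO mouse 3 at 0.019 lies below WT mouse 4 at 0.047.

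The list of megakaryocyte and platelet genes was higher in KO and that of erythroid genes lower, by camera with the preset correlation (adjusted p = 0.00224 and 0.0237) and by fry (0.0246 for each). Neither passed camera otherwise (adjusted p = 0.137 and 0.216 with an estimated correlation). The estimated correlations were -0.007 and -0.06, below the preset 0.01, so a higher correlation among the genes was not the reason. Of 13 measured megakaryocyte genes, 2 rose and 1 fell over all genes, and the median log2 fold change was 0.50. Gp1ba rose from 39.6 ± 5.60 to 88.1 ± 14.3 CPM, Itga2b, the integrin CD41, from 52.98 ± 12.6 to 105 ± 15.2 CPM, and Thbs1 fell from 34.4 ± 9.95 to 8.95 ± 2.18 CPM (SD, n = 4, edgeR adjusted p = 0.00128, 0.00737 and 0.00173). With Selp and Gp1bb, 4 were higher, and 1 lower, adjusted over the list alone. Of 10 measured erythroid genes, 1 fell over all genes, the carbonic anhydrase gene Car2, from 2286 ± 111 to 1306 ± 84.9 CPM (SD, n = 4, edgeR adjusted p = 4.19e-06). Car1 brought the lower genes to 2 adjusted over the list alone, at 8.11 ± 4.59 CPM in WT and 1.93 ± 1.30 CPM in KO. The other 8 did not pass, among them Gata1 at a log2 fold change of 0.44 and Tfrc at 0.04. The median of the list was -0.19, and -0.02 with the stricter filter or -0.014 with thinned counts. Haemoglobin genes were listed at 0 throughout. The erythroid camera call was lost without WT mouse 2 (adjusted p 0.054), KO mouse 1 (0.0945) or KO mouse 3 (0.0613), with the stricter filter (0.0746) and with thinned counts (0.0876).

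Of 36 genes characteristic of haematopoietic stem cells, 0 passed edgeR's test over all genes. At an unadjusted p under 0.05, 3 were higher and 9 lower, DESeq2 called 2 higher and 1 lower, and limma voom 1 higher. Adjusted over the list alone, 2 were higher, Vwf (197 ± 34.96 CPM in WT and 282 ± 30.2 CPM in KO) and Ly6a (47.9 ± 14.1 and 81.0 ± 6.52 CPM), which encodes Sca-1. A further 4 were lower adjusted over the list alone, namely Mecom (336 ± 27.0 and 251 ± 23.9 CPM), Mllt3, Kit and Hlf, with log2 fold changes of -0.43, -0.35, -0.30 and -0.28. The list did not pass camera (adjusted p = 0.0728). Camera tests for a shared direction, so it cannot decide whether genes of the list changed in both directions. Of 10 genes of multipotent and lymphoid-primed progenitors, 0 passed over all genes. In this list 1 gene, Cd37, was higher and 1 was lower adjusted over the list alone, with a camera adjusted p of 0.38.

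Among markers of other marrow cells, those of macrophages and dendritic cells went in both directions. Of 6 measured, Cd68 rose from 6.58 ± 3.31 to 19.9 ± 4.19 CPM and Cd74 from 37.0 ± 19.1 to 86.5 ± 22.4 CPM, while Mrc1, the mannose receptor, fell from 6.09 ± 3.96 to 0.989 ± 0.602 CPM (SD, n = 4, edgeR adjusted p = 0.0347, 0.0371 and 0.02). Adjusted over the list alone, 4 were higher, with the MHC class II genes H2-Aa and H2-Ab1, and 2 lower, with Vcam1. The list's median log2 fold change was 0.69 and its mean -0.043, so the 2 differed in sign; camera gave an adjusted p of 0.0328, against adjusted p = 0.312 with an estimated correlation and 0.187 by fry. C1qa, C1qb and C1qc, known from macrophages, and Siglech, known from plasmacytoid dendritic cells, had together at most 44 counts in any library. Siglech was listed at 0 in every library. The camera call was lost without WT mouse 2 (adjusted p 0.108) or WT mouse 3 (0.0973), without a filter (0.513), with DESeq2 (0.0607) and with length and GC offsets (0.0538), and the Mrc1 call in 7 of 17 alternatives.

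Other markers gave no call. Of 8 neutrophil and monocyte genes (Prtn3 with the smallest p, 16.2 ± 4.69 and 11.0 ± 2.79 CPM) and 6 of stroma and endothelium (Pdgfrb, 5.76 ± 3.37 and 3.41 ± 1.42 CPM), 0 passed, and the camera adjusted p were 0.379 and 0.932. The median log2 fold changes of these lists were 0.185 and -0.077, so Prtn3 went against its list. Among B, T and NK cell markers 4 of 20 were measured and among mast cell, basophil and eosinophil markers 1 of 13, too few for a test of the list. Cd4 was at 2.36 ± 1.47 and 5.10 ± 3.82 CPM and Cpa3 at 4.79 ± 3.34 and 2.59 ± 0.648 CPM.

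Of 24 genes of H3K9 methylation and silencing, Atf7ip alone passed over all genes. Adjusted over the list alone, 3 were lower, with the DNA methyltransferase gene Dnmt3a (log2 fold change -0.51) and Fam208a, a subunit of the HUSH silencing complex (-0.52). Camera gave an adjusted p of 0.0728, with a median of -0.003 and a mean of -0.092. Of 21 other histone demethylase genes 0 passed. Kdm5d, a Y-linked H3K4 demethylase, had the smallest p, at 109 ± 15.4 CPM in WT and 77.2 ± 15.7 CPM in KO, and camera gave an adjusted p of 0.101. Of 14 imprinted genes 0 passed over all genes, and Igf2r (119 ± 13.4 and 75.8 ± 19.3 CPM) was lower adjusted over the list alone; at an unadjusted p under 0.05, 2 were lower, DESeq2 called 1, and the camera adjusted p was 0.706.

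Bcl2, which blocks apoptosis, rose 1.54-fold, from 611 ± 54.9 to 936 ± 207 CPM (SD, n = 4, adjusted p = 0.0137 by edgeR's quasi-likelihood test), the 1 gene past the threshold among 19 of the BCL-2 family and caspases. It was also the 1 higher gene adjusted over the list alone, and the list did not pass camera (adjusted p = 0.562). The call was lost in 3 of 19 alternatives, those without WT mouse 3, WT mouse 4 or KO mouse 3, with edgeR adjusted p of at most 0.0574. Of 23 p53 target genes 0 passed over all genes, and Zmat3 (91.8 ± 19.8 and 144 ± 37.0 CPM) was higher adjusted over the list alone. The median of the p53 list was -0.057 and its mean 0.111, with a camera adjusted p of 0.562.

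The list of 40 nuclear genes of oxidative phosphorylation was higher by camera (adjusted p = 0.0224), which became adjusted p = 0.493 with an estimated correlation, and 0.297 by fry. Its median log2 fold change was 0.14, 28 of the 40 had a fold above 1, and 0 passed edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 4 were higher; DESeq2 called 0 and limma voom 1. Atp5b, the ATP synthase beta subunit, was at 1448 ± 255 CPM in WT and 1843 ± 138 CPM in KO. The list's call was lost without WT mouse 1, 2 or 3 or KO mouse 1, with limma voom and with length and GC offsets. Of 22 glycolysis and hypoxia genes (Ldha, 730 ± 108 and 949 ± 152 CPM), 22 immediate early and stress genes (Egr2, 1.79 ± 0.966 and 3.73 ± 3.796 CPM), 36 DNA repair genes (Prkdc, 209 ± 11.9 and 268 ± 6.69 CPM) and 16 histone genes (Hist1h2bb, 20.1 ± 10.6 and 9.57 ± 3.37 CPM), 0 passed over all genes or adjusted over the list alone. Their camera adjusted p were 0.411, 0.0656, 0.31 and 0.174. The median log2 fold changes were -0.125, -0.193, 0.046 and -0.246, so Ldha and Egr2 went against their lists. In the first 2 lists, 13 of 22 and 17 of 22 genes had a fold below 1. Egr2 had 33 and 130 counts in KO mice 2 and 3, and 3 and 6 in KO mice 1 and 4.

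Altogether 13 of the 25 lists, with 276 measured genes, had no member called by edgeR, DESeq2 or limma voom. At an unadjusted p under 0.05, 20 of their genes were higher and 10 lower by edgeR. By camera with the preset correlation 7 of 22 lists passed, 6 higher and 1 lower. With an estimated correlation 0 passed, 3 having an unadjusted p under 0.05, and by fry 3 passed. Without WT mouse 2 the count by camera was 4.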

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

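Among 148 groups of 4 values, 10 had a library set apart from the other 3 by a gap that takes up most of the range. By chance about 1 in 20 groups, or 7.4, would. The total of KO mouse 3 was 14872493 counts, against 5541504 to 7059382 in the other KO libraries. Rn45s took 3.93% of the counts of KO mouse 4, against 2.37% to 2.49% in the others. Kdm4d was at 1.76 CPM in WT mouse 3, and at 0 to 0.173 CPM in the other WT libraries. Slfn5 was at 80.6 CPM in WT mouse 2, below 120 to 124 CPM in the other WT libraries. Thbs1 was at 19.5 CPM in WT mouse 4, below 38.2 to 40.4 CPM. Dnah8 was at 118 CPM in WT mouse 2, below 149 to 153 CPM. Zcchc3 was at 28.3 CPM in WT mouse 1, below 46.8 to 47.0 CPM. Dpp4 was at 65.2 CPM in WT mouse 2, above 47.4 to 48.9 CPM. Hist1h2bb was at 35.9 CPM in WT mouse 1, above 14.0 to 15.3 CPM. The mean centred log2 level of the p53 target list was 0.148 in KO mouse 3, above 0.002 to 0.012 in the other KO libraries.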

How the results depend on the processing

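All 67 genes that differed kept their sign in every alternative in which they were tested. Of 867 fold changes of named genes under alternatives, 782 stayed on their side of the threshold with the same sign, 66 were no longer past it, 19 newly passed it and 0 changed sign. Other scaling gave 64 genes with DESeq2 size factors and 64 with library totals. The stricter filter and the legacy method gave 64 each, limma voom 74, offsets for length and GC 68, thinned counts 77, and removal of ribosomal RNA 62. Without a filter on low counts, 199 genes passed, 109 higher and 90 lower (54.8% higher against 43.3%), among them all 67; the added calls came with 18440 genes tested. DESeq2 called 154 genes, 78 higher and 76 lower, among them all 67. It also called Kdm4a at a log2 fold change of -0.849 (adjusted p 0.0463, in a range of 0.0463 to 0.474 over the alternatives for Kdm4a). The cause of the higher count was not tested. DESeq2 had more false calls on simulated counts, but these were drawn with edgeR's own dispersions. A threshold of adjusted p 0.1 gave 125 genes (66 and 59), and a log2 fold change above 1 gave 38 (15 and 23). Leaving out 1 library gave 35 to 70 genes, 14 to 33 higher and 21 to 38 lower, with fewer samples; the lowest came without WT mouse 3. The lists past camera numbered 4 to 10 without 1 library, 0 with an estimated correlation and 3 by fry. Without the filter, the median of the macrophage and dendritic list turned to -0.897 (adjusted p 0.513), since more of its rarely counted genes then entered. The common biological coefficient of variation was 0.281. Thinning to the smallest total left 10863 genes to test, against 11498, but did not lower the count of calls.

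The mouse numbers shared by the groups were tested as a pairing. Same-numbered mice had deviations from their group means correlated at -0.092 to -0.009, and 0 of 8 libraries correlated best with its own number, so the numbers were not taken to pair the mice. With the replicate number as a block, 57 genes passed (25 higher, 32 lower), 50 of them among the 67, and 7 lists.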

Other observations

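Some genes past the threshold fell outside the rule for named genes, and those named in this paragraph were chosen after their values were seen. A pair of chaperone genes rose, Hspd1 of mitochondria by 0.49 and Hsp90b1 of the endoplasmic reticulum by 0.46 on the log2 scale (edgeR adjusted p 0.024 and 0.0284). Iigp1, a GTPase gene induced by interferon, rose by 0.80, Serpina3g by 0.63 and Lgals9, which encodes galectin-9, by 0.52 (edgeR adjusted p 0.0278, 0.043 and 0.0492). Podxl, a sialomucin gene, rose by 0.88 and Slc14a1, a urea transporter, by 0.62 (edgeR adjusted p 0.0254 and 0.00641). The transcription factor genes Sox6 and Sall2 had log2 fold changes of -0.85 and -1.11, and Eea1, an early endosome gene, of -0.86 (edgeR adjusted p 0.0142, 0.0228 and 0.000581). Spop, a substrate adaptor of a ubiquitin ligase, was at -0.60, and Adam10, a membrane protease, at -0.62 (edgeR adjusted p 0.00991 and 0.00641).

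Of the tests that follow, those on DNA flanking the targeted genes and all 3 on the interferon genes were chosen after the result was seen. The count of 67 genes was compared with the other ways to divide the 8 libraries into 4 and 4. Of the 35 divisions, 1, the real one, gave as many, and the highest other count was 4. This is the smallest share that 35 divisions can give, so chance is argued against as the source of the count but not excluded. The other divisions mix WT and KO libraries, which adds spread within their groups. A difference other than the knockout that follows genotype would give the same result. Knockout mice can carry DNA of another strain around the targeted genes. Of the 66 other genes, 65 lay more than 10 Mb from Kdm4a, Kdm4b and Kdm4c, 0 lay closer and 1 had no position. This argues against DNA within 10 Mb as the source of most calls. The 3 windows held 261 tested genes and 11164 lay elsewhere, so few calls would fall in them from a cause spread over the genome. An unadjusted p under 0.05 by edgeR was seen for 10.7% of genes in them and 11.2% elsewhere. Strain-derived DNA farther away was not tested. For the count of 7 lists, 4 of the 35 divisions gave as many, and the highest other count was 9, so chance is not excluded for the lists. The agent that induced the knockout, and whether WT mice received it, are not given in the sources used here, so an effect of the treatment stays open.

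Of the interferon-stimulated genes 20 of 29 were higher adjusted over the list alone, while the list did not pass camera otherwise (adjusted p = 0.137 with an estimated correlation). Greater depth of the KO libraries is argued against, since with every library thinned to the smallest total the list's median log2 fold change was 0.574, against 0.549. Macrophages in the sort are argued against as the whole source by C1qa, C1qb and C1qc, which are abundant in them. Together with Siglech these genes reached at most 2.97 CPM in a KO library, while Ifi44 rose by 179 CPM. Siglech, the only marker used for plasmacytoid dendritic cells, was listed at 0 in every library, as were the globin genes. The test therefore cannot decide for plasmacytoid dendritic cells, which stay open. Other antigen-presenting cells were not tested and stay open, since Cd68 and Cd74 rose too and the MHC class II gene H2-Aa was at 28.9 CPM in WT and 54.1 CPM in KO. Chance is not excluded, since 2 of the 35 divisions gave a median as far from 0; the other, 0.598, set WT mice 1, 2 and 3 with KO mouse 3, and an effect of the lost demethylases or of the induction treatment may each account for the rise.

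Genes with a symbol of Zfp and a number were tested as a group. Many zinc finger proteins repress transcription through H3K9 methylation, and that mark is a substrate of the targeted enzymes. The group was set by symbol alone, without regard to whether a gene acts through H3K9 methylation. It took in Zfp36, for instance, which is also in the list of immediate early and stress genes. The group was not among the lists fixed before the data were examined. Of 302 tested, 171 had a fold below 1 and 4 fell (Zfp518a, Zfp951, Zfp445 and Zfp280d) while 1 rose (Zfp280c); at an unadjusted p under 0.05, 34 were lower and 7 higher. Gene length and GC content are argued against, since with offsets for both the median lay at -0.076 relative to other genes (95% bootstrap interval -0.109 to -0.016). The bootstrap resampled the Zfp genes and not the mice, so its interval does not measure the spread between mice. Expression level is argued against too, since the group's median of -0.073 lay below the 2.5th percentile, -0.046, of 10000 gene sets matched on expression. These sets also vary the genes and not the mice. Chance is not excluded, as 2 of the 35 divisions gave a difference as far from 0 as the real -0.076, the other being -0.1, so a lower level of these genes after loss of the enzymes may be real but is a hypothesis only.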
